A study of Mus musculus with 48 samples.

How the data were processed

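RNA from mouse livers was measured by sequencing of poly(A) RNA in 48 libraries, 1 per pup. Per the labels, C57Bl/6J dams drank water with 0 or 50 ppm cadmium chloride from 4 weeks of age, were mated at 9 weeks with CAST/EiJ males that were not exposed, and stayed on that water until the pups reached postnatal day (PND) 10. Livers were taken at PND0 and PND21, so the older pups had been off cadmium since PND10. A dose of 1 ppm named in the labels was not analysed here. Libraries were grouped by age, dose and sex into 8 groups of 6. One control male library (replicate 3) has PND0 in its title and source and PND21 in its age label; it was used as PND0, and was left out in an alternative. Litters and dams are not given in the sources used here, so the p-values measure spread between pups and not between litters.

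The authors deposited 1 table of raw counts, whole-number reads per Ensembl gene with 1 column per library and 55487 genes. The labels name FastQC, STAR, HTSeq and DESeq2, without versions. The genome build, the annotation and the strand setting are not given in the sources used here, so no gene positions are printed. The kit marks strands; without the counting setting, reads of overlapping genes on opposite strands stay uncertain. Reads shared between close relatives, such as the Mup, Stfa and Hba genes or Hamp and Hamp2, are uncertain too. Symbols were found for 55141 gene IDs. The other 346 IDs hold 0.0391% of counts, and 213 gene IDs share their symbol with another ID. Depth ranged from 57.5 to 91.4 M (mega) counts per library. No columns were left unmapped. No identical libraries were found among 120 pairs within groups, where the lowest chi-square per degree of freedom between libraries was 20.9.

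Comparisons used R 4.3.3 with edgeR 4.0.16: filterByExpr by group, TMM scaling, robust dispersions, and 2-sided quasi-likelihood F-tests on group means. Adjusted p-values are Benjamini-Hochberg values over all genes tested in a comparison, with a threshold of 0.05. The 24 libraries of each age were fitted together, and all 48 where ages were compared. The effect for both sexes is the mean of the female and male effects. Sex and age differences in the effect were tested as interactions. Log2 fold changes are given with standard errors (SE). CPM is counts scaled to TMM-adjusted library sizes within an age, unless stated otherwise, with standard deviations (SD). The procedure was tested on simulated data with known changes, placed only in genes with a mean above 1 CPM. With 6 libraries per group it found 55.2% of genes changed 1.5-fold at PND0 and 62.7% at PND21, 85.1% and 91% of those changed 2-fold, and 100% of those changed 4-fold, with 7.45% and 4.19% false calls. How many changed genes it finds at lower counts was not measured. The 7.45% at PND0 lies above the nominal 5%. Counts were simulated for each gene separately, without variation between libraries that many genes share. The simulated rates may therefore not hold for the real libraries.

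Before the data were examined, the comparisons, the tests, the alternative settings other than those added later, the rule for named genes and 43 gene lists (841 genes) of pathways, cell types and other tissues were fixed. The lists hold 877 entries because some genes stand in more than 1; 7 genes are not in the table. Lists with at least 5 tested genes were compared with all other genes by camera in limma 3.58.1, with a preset correlation of 0.01 and, beside it, with an estimated correlation. Their adjusted p-values run over the lists of a comparison. Fry was run too. It tests whether genes of a list move, on balance, 1 way, and compares nothing with other genes. Named genes are Plagl1, Mt1, Mt2, Slc39a8, Hamp, Tfrc, Igf2, H19, Cdkn1c and Dlk1 in every cadmium comparison; the 6 largest rises and 6 largest falls past the threshold with a mean of at least 2 CPM in the higher group, leaving out clone, predicted and pseudogene names (5 and 5 for age and sex); up to 4 members per list past the threshold with the smallest p; and, where under 6 genes pass, all of those and the 3 smallest p. Genes named outside this rule are said to be chosen after their values were seen.

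Alternatives were DESeq2 1.42.0, RLE scaling in edgeR, no low-count filter, a filter of 1 CPM in every library of a group, limma-voom with quality weights, fits on 12 or on 48 libraries, leaving out the library with conflicting age labels and leaving out each library in turn. Added after seeing the data were a covariate for the first principal component of variation within groups, leaving out 5 PND0 libraries whose skeletal muscle or pancreas markers summed to above 100 CPM, and leaving out 5 PND0 libraries whose fatty acid oxidation genes summed to under 10000 CPM. Each count of genes was set against 100 splits of the same libraries. Some genes that the rule names are not reported here.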

Results

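Liver RNA of C57Bl/6J x CAST/EiJ pups was counted in 8 groups of 6 libraries: control or 50 ppm cadmium chloride, PND0 or PND21, female or male. At PND0, totals ranged from 60.6 to 83.2 M (mega) counts in control females, 58.7 to 79.7 in control males, 64.4 to 82.1 in exposed females and 59 to 72.8 in exposed males. At PND21 they ranged from 65.5 to 83.8, 61.4 to 75.5, 57.5 to 74.9 and 63.9 to 91.4 M in the same order. The title of the series names the imprinted gene Zac1 (Plagl1) and fatty liver after cadmium exposure during development. The comparisons therefore ask how liver genes, imprinted genes among them, differed with exposure at birth and at PND21, after exposure had ended at PND10.

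Sex and age labels were checked against the counts. Xist, expressed from the inactive X chromosome, was at least 328 CPM in all 24 female libraries and at most 0.307 CPM in the males. The Y-linked gene Ddx3y was at least 91.6 CPM in all 24 male libraries and at most 0.0593 CPM in the females. All 48 libraries lay closer to the mean profile of the age in their title. The library with conflicting age labels (PND0 control male replicate 3) correlated across genes at 0.988 with the PND0 profile and 0.852 with the PND21 profile; genes are not independent replicates.

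At PND21, livers of exposed pups carried far more of the transcripts typical of fetal liver than those of controls, in both sexes. H19 (ENSMUSG00000000031), an imprinted noncoding RNA that falls after birth, rose by a log2 change of 4.49 ± 0.44 (SE, adjusted p = 5.54e-08, 12 exposed and 12 control libraries). The fetal growth factor Igf2 (ENSMUSG00000048583) rose by 3.85 ± 0.50 and Dlk1 (ENSMUSG00000040856), a Notch-like protein of fetal hepatoblasts, by 3.86 ± 0.31. Plagl1 (ENSMUSG00000019817), the zinc finger factor Zac1, rose less, by 0.76 ± 0.14 (adjusted p = 8.47e-05). In each of these 4 genes all 12 exposed libraries lay above the control mean. In females H19 averaged 2114 ± 1100 CPM (SD, n = 6) in exposed and 128 ± 116 in control pups, and in males 1322 ± 879 and 43.2 ± 17.7. Plagl1 averaged 4.64 ± 0.791 against 3.03 ± 0.413 CPM in females and 4.46 ± 1.70 against 2.38 ± 0.607 in males. Igf2 and Dlk1 stayed low, at 2.27 ± 1.57 and 1.54 ± 0.658 CPM in exposed females.

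Of the 18 tested genes of the imprinted network linked to Plagl1, 14 rose, 1 fell and 3 did not pass, and adjusted over the list alone 15 rose and 1 fell. Peg10 rose by 1.66 ± 0.14 and Mest by 1.67 ± 0.18. The list moved up against other genes (adjusted p = 3.61e-08; adjusted p = 0.115 with an estimated correlation). The cell cycle inhibitor Cdkn1c rose by 0.84 ± 0.17 (adjusted p = 3.09e-04), a call that ended with the within-group component as a covariate (0.20, adjusted p = 0.261, the highest over all settings, against 4.6e-06 as the lowest). Of 28 other imprinted genes 5 rose, 9 fell and 14 did not pass. All 17 tested fetal hepatocyte genes rose (adjusted p = 0.0408 with an estimated correlation). Examples are Cd24a, a surface protein of hepatic progenitors, by 2.52 ± 0.19 and the proteoglycan gene Gpc3 by 1.80 ± 0.15. Of 42 mature hepatocyte genes 34 fell, 2 rose and 6 did not pass, alike when adjusted over the list alone (adjusted p = 0.0276 with an estimated correlation). Aldh1a1, a retinaldehyde dehydrogenase, changed by -1.27 ± 0.08 and the glutamine synthetase gene Glul by -0.79 ± 0.07. The largest falls included the sulfotransferase gene Sult3a1 at -6.42 ± 0.54, the fatty acid elongase gene Elovl3 at -4.12 ± 0.53 and the major urinary protein genes Mup17 at -7.06 ± 0.98 and Mup2 at -4.10 ± 0.41.

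**Figure D1:**
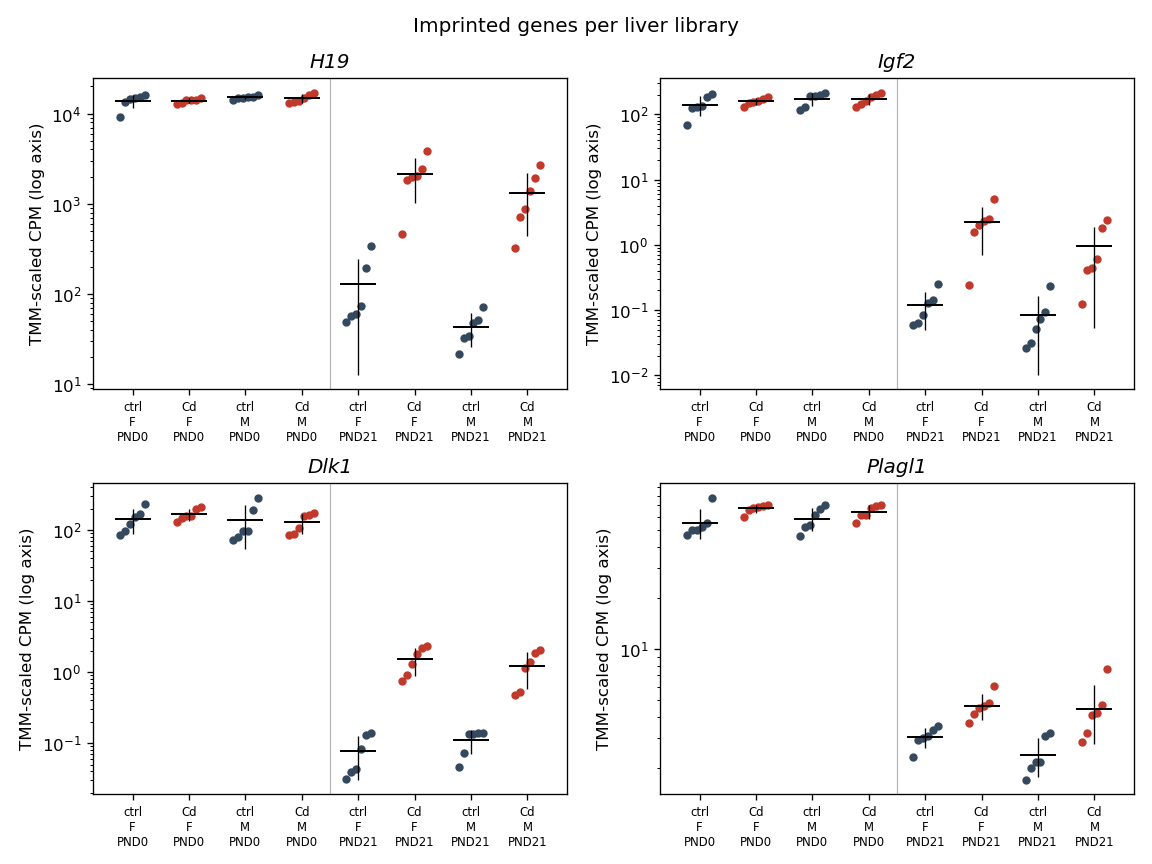
Imprinted genes H19, Igf2, Dlk1 and Plagl1 in CPM on a log axis, with 1 point per library by age, sex and dose (dark control, red exposed, 6 per group, placed in order of value); horizontal lines are means and vertical bars SD, with zeros and lower ends of bars drawn at 0.01 CPM. At PND21 mean H19 was 2114 CPM in exposed females and 1322 in exposed males, against 128 and 43.2 in controls.

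Transcripts of blood cell lineages were also higher at PND21. All 14 megakaryocyte, platelet and mast cell genes rose (adjusted p = 0.0111 with an estimated correlation), among them the platelet chemokine gene Ppbp by 3.72 ± 0.19 and Vwf, the von Willebrand factor gene, by 2.10 ± 0.10. All 19 neutrophil genes rose (adjusted p = 1.50e-22; adjusted p = 0.0504 with an estimated correlation), among them Mpo, which encodes myeloperoxidase, by 3.97 ± 0.33. Of 28 erythroid genes 24 rose and 0 fell, with 25 adjusted over the list alone (adjusted p = 8.21e-15; adjusted p = 0.199 with an estimated correlation). The Rh-associated glycoprotein gene Rhag rose by 4.92 ± 0.41. Of 14 B lineage genes 10 rose and 0 fell, and adjusted over the list alone 10 rose and 1 fell (adjusted p = 0.00415; adjusted p = 0.264 with an estimated correlation). Rag1, needed to rearrange antigen receptors, rose by 2.39 ± 0.32. Of 19 macrophage and Kupffer cell genes 16 rose and 0 fell, with 17 adjusted over the list alone (adjusted p = 3.99e-10; adjusted p = 0.133 with an estimated correlation), such as the scavenger receptor gene Marco by 2.25 ± 0.17. Of 13 T and NK cell genes 4 rose, 1 fell and 8 did not pass. Among the largest rises were the eosinophil genes Epx by 6.68 ± 0.80 and Prg2 by 5.69 ± 0.65.

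Growth, matrix and oxygen-related groups rose together at PND21. Of 31 cell cycle genes 29 rose and 0 fell, also adjusted over the list alone (adjusted p = 1.08e-14; adjusted p = 0.191 with an estimated correlation), with Rrm2, a subunit of ribonucleotide reductase, at 2.04 ± 0.16. Of 23 extracellular matrix genes 22 rose and 0 fell, also adjusted over the list alone (adjusted p = 7.82e-17; adjusted p = 0.0504 with an estimated correlation), with periostin (Postn) at 1.40 ± 0.08. Of 17 stellate cell genes 11 rose and 1 fell (adjusted p = 1.98e-04; adjusted p = 0.233 with an estimated correlation), with Col1a1 at 0.83 ± 0.12. Of 19 hypoxia genes 18 rose and 0 fell, also adjusted over the list alone (adjusted p = 0.0301 with an estimated correlation). The lactate dehydrogenase gene Ldha rose by 1.14 ± 0.08 and the oxygen sensor gene Egln3 rose too. Erythropoietin (Epo) gave 14 and 1 counts over the 6 control females and 6 control males, and 695 and 596 over the exposed groups. Fgf23, a phosphate-regulating hormone gene, rose by 7.32 ± 0.69. Of 15 growth hormone and IGF genes 8 rose and 2 fell (adjusted p = 0.00132; adjusted p = 0.191 with an estimated correlation), with Igfbp2 at 1.44 ± 0.11. Of 13 p53 targets 7 rose and 0 fell (adjusted p = 0.0223; adjusted p = 0.215 with an estimated correlation), and of 18 immediate early genes 9 rose and 0 fell (adjusted p = 0.00975; adjusted p = 0.430 with an estimated correlation).

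Lipid genes went both ways at PND21. Of 23 sterol synthesis genes 20 fell and 0 rose, with 22 adjusted over the list alone (adjusted p = 0.0301 with an estimated correlation), among them Idi1, isopentenyl diphosphate isomerase, at -2.23 ± 0.23 and Cyp51, lanosterol demethylase, at -1.72 ± 0.17. Of 19 bile acid genes 10 fell and 3 rose (adjusted p = 0.00136; adjusted p = 0.180 with an estimated correlation), with the hydroxylase gene Cyp7b1 at -1.82 ± 0.15. Of 17 lipid droplet genes 7 rose and 3 fell, with the fatty acid carrier genes Fabp4 at 1.99 ± 0.13 and Cd36 at 1.10 ± 0.08. Of 22 lipogenesis genes 9 rose and 5 fell, with the desaturase gene Fads1 at -0.79 ± 0.08 and Pparg at 1.32 ± 0.13. Of 31 fatty acid oxidation genes 9 rose, 5 fell and 17 did not pass, and of 19 glucose and glycogen genes 8 rose, 3 fell and 8 did not pass.

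Metal and iron genes at PND21 moved singly. Metallothionein genes Mt1 (0.08 ± 0.12, adjusted p = 0.618, higher in 5 of 12 exposed libraries) and Mt2 (0.28 ± 0.22, adjusted p = 0.33) did not pass. In the metal transport list 4 of 11 rose and 2 fell, including the zinc transporter gene Slc39a5 at 2.27 ± 0.22 and the zinc and cadmium importer gene Slc39a8 at -0.35 ± 0.05. In the iron list 9 of 21 rose and 6 fell, including haem oxygenase (Hmox1) at 1.23 ± 0.10 and the transferrin receptor gene Tfrc at 0.84 ± 0.18 (higher in 11 of 12 exposed libraries). Hepcidin (Hamp), at most 0.245 CPM, was too low to test at PND21. Its relative Hamp2, named here after its values were seen, fell by 2.67 ± 0.53 on the log2 scale (adjusted p = 2.19e-04), from 0.469 CPM in control to 0.0415 in exposed females and from 0.157 to 0.0385 in males.

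Rises and falls at PND21 numbered 6 and 2 of 16 endothelial, 2 and 8 of 22 interferon, 3 and 2 of 23 acute phase, 8 and 7 of 20 NRF2, 8 and 6 of 19 drug metabolism, 1 and 2 of 12 heat shock, 5 and 3 of 19 unfolded protein, 1 and 6 of 16 clock, 0 and 10 of 28 respiratory chain and 0 and 4 of 28 ribosomal protein genes. They numbered 5 and 12 of 28 genes with adult sex bias (adjusted p = 0.00971; adjusted p = 0.215 with an estimated correlation) and 0 and 2 of 10 sex chromosome genes. The respiratory chain list moved down (adjusted p = 0.0134; adjusted p = 0.624 with an estimated correlation). The share of counts from mitochondrial transcripts was 4.96% ± 0.293 (SD, n = 6) in exposed and 4.34% ± 0.180 in control females, and 4.37% ± 0.316 and 3.85% ± 0.287 in males. Bile duct genes gave 0 of 11 past the threshold in edgeR. Markers of other tissues that could be tested gave 2 rises of 3 for fat, 0 of 2 for muscle, 1 rise and 1 fall of 3 for pancreas, 2 rises and 1 fall of 5 for gut and 1 rise of 2 for kidney and adrenal. The gut list summed to 4672 ± 1717 CPM (SD, n = 6) in exposed and 480 ± 124 in control females, and to 3261 ± 933 and 578 ± 169 in males. Most of that sum is Apoa4, an apolipoprotein gene that liver expresses too, which rose by 2.96 ± 0.18 (SE) and was higher in 12 of 12 exposed libraries. Scaled by TMM within the age, where list sums are on library totals, Apoa4 averaged 4716 CPM in exposed and 449 in control females. The rise in the kidney and adrenal list is Cyp11a1, the side-chain cleavage enzyme of steroid synthesis, at 5.73 ± 0.69. The median was above 0 while the test pointed down in the NRF2, drug metabolism, acute phase and bile duct lists, and the reverse held for fatty acid oxidation; none of these 5 passed the list test (adjusted p = 0.289, 0.913, 0.938, 0.845 and 0.970).

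Over both sexes, 4064 genes rose and 3363 fell at PND21 of 17527 tested, 1157 and 336 of them at least 2-fold. Adjusted over the list alone, 28 of 43 lists gave equal counts and none gained more than 3 members. In females 2832 rose and 1932 fell, and in males 2939 rose and 1998 fell. Of these, 3347 genes passed in both sexes, and 3346 of them in the same direction (2185 up and 1161 down, against 475 and 220 expected for independent calls). The sexes share 1 fit with common dispersions and may share litters, so their calls are not independent. Log2 changes in the sexes correlated across genes at r = 0.867 and rho = 0.743; genes are not independent replicates. H19 rose by 4.04 ± 0.61 in females and 4.93 ± 0.64 in males, Igf2 by 4.21 ± 0.70 and 3.49 ± 0.73, Dlk1 by 4.26 ± 0.45 and 3.46 ± 0.43, and Tfrc by 0.89 ± 0.25 and 0.79 ± 0.25. Fetal hepatocyte genes rose in 14 of 17 cases in females (17 adjusted over the list alone) and 15 of 17 in males, and mature hepatocyte genes fell in 26 and 28 of 42. Plagl1 rose by 0.61 ± 0.20 in females (adjusted p = 0.0207) and 0.91 ± 0.20 in males (adjusted p = 0.0011). The female call for Plagl1 ended without exposed female replicate 46 (0.52, adjusted p = 0.0588) and with the covariate (0.43, adjusted p = 0.156), with a lowest adjusted p of 0.00401 over the settings. The Tfrc call ended in females with the covariate (adjusted p = 0.0763, lowest 0.00172), and in males with it (0.179), without a filter (0.0527) and without exposed male replicate 30 (0.0577, lowest 0.003).

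No gene differed in its cadmium effect between the sexes at PND21 by edgeR, with 860 genes at an unadjusted p under 0.05, 1 gene by DESeq2 and 0 by limma-voom. The smallest p belonged to Ism2, with a female minus male difference of -2.53 ± 0.51 (adjusted p = 0.676). For Cdkn1c, past the threshold in males (1.06 ± 0.24, adjusted p = 0.00178) and not in females (0.61 ± 0.24, adjusted p = 0.0596), the difference was -0.45 ± 0.34 (adjusted p = 0.999). The male Cdkn1c call ended with the covariate (0.36, adjusted p = 0.128, lowest 8.63e-05). In females the settings gave adjusted p for Cdkn1c from 0.0243, past the threshold, to 0.911.

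At birth the response was smaller, and part of it was shared with PND21. Of the 554 genes past the threshold at PND0 and tested at PND21, 352 passed at both ages. Of these, 232 moved in the same direction and 120 in opposite directions. At PND0, hepcidin (Hamp, ENSMUSG00000050440), the hormone that limits iron export, changed by -4.57 ± 0.62 (log2, SE, adjusted p = 1.92e-04, 12 exposed and 12 control libraries) and Hamp2 by -4.21 ± 0.59. Mt1 (ENSMUSG00000031765) changed by -1.81 ± 0.23 (adjusted p = 5.53e-05) and Mt2 (ENSMUSG00000031762) by -1.83 ± 0.24 (adjusted p = 1.3e-04); both are metal-binding proteins. Tfrc (ENSMUSG00000022797) rose by 0.71 ± 0.12 (adjusted p = 0.00121). In these 5 genes all 12 exposed libraries lay on the same side of the control mean. Mt1 averaged 868 ± 442 CPM (SD, n = 6) in control and 203 ± 93.8 in exposed females, and 943 ± 296 and 329 ± 72.3 in males. Hamp averaged 43.3 ± 49.9 and 18.4 ± 16.6 CPM in control females and males and 1.21 ± 1.60 in exposed males. The imprinted genes named for PND21 did not pass: Plagl1 gave 0.21 ± 0.08 (adjusted p = 0.148, from 0.0354 to 0.286 over the settings, higher in 11 of 12 exposed libraries), Igf2 0.07 ± 0.14, H19 -0.02 ± 0.07, Dlk1 0.06 ± 0.22 and Cdkn1c -0.33 ± 0.36. Plagl1 passed in 1 setting, without the 5 libraries with markers of other tissues (0.27, adjusted p = 0.0354). Without the 5 libraries with low fatty acid oxidation sums Cdkn1c was 0.62 (adjusted p = 0.0785) and Dlk1 0.49 (adjusted p = 0.063), the lowest over their settings (highest 0.997 and 1). In the imprinted network list 0 of 18 passed by edgeR, over all genes or adjusted over the list alone, and 3 had an unadjusted p under 0.05; without those libraries 1 rose, and 4 rose and 1 fell adjusted over the list alone.

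Of 20 hypoxia genes at PND0, 9 rose, 1 fell and 10 did not pass, and adjusted over the list alone 15 rose and 1 fell (adjusted p = 0.00358 with an estimated correlation). The hydroxylase gene P4ha1 rose by 0.90 ± 0.11 and the glycolytic gene Pgk1 by 0.65 ± 0.08. The member that fell is Mt1. In the iron list 1 of 22 rose and 5 fell, and adjusted over the list alone 3 rose and 7 fell (adjusted p = 0.0132; adjusted p = 0.0597 with an estimated correlation), with the ferroxidase gene Cp at -0.68 ± 0.12. Of 11 metal genes 2 rose and 3 fell (3 and 4 adjusted over the list alone), with the zinc exporter gene Slc30a1 at -0.57 ± 0.11. Of 19 macrophage and Kupffer cell genes 4 fell and 0 rose, and adjusted over the list alone 10 fell (adjusted p = 0.0195 with an estimated correlation). Cd5l, a macrophage-secreted protein gene, changed by -0.89 ± 0.10 and the Kupffer cell lectin gene Clec4f by -0.39 ± 0.08. Of 16 endothelial genes 1 rose and 1 fell, and adjusted over the list alone 1 rose and 6 fell (adjusted p = 0.00829; adjusted p = 0.569 with an estimated correlation), with the sinusoidal lectin gene Clec4g at -0.97 ± 0.13. Of 28 respiratory chain genes 8 rose and 0 fell, and adjusted over the list alone 24 rose (adjusted p = 5.01e-18; adjusted p = 0.237 with an estimated correlation), with Ndufs1 at 0.34 ± 0.07. The mitochondrial share of counts was 3.41% ± 0.372 (SD, n = 6) in exposed and 2.88% ± 0.347 in control females, and 3.40% ± 0.484 and 2.84% ± 0.254 in males.

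Of 40 mature hepatocyte genes at PND0, 5 fell and 0 rose, and adjusted over the list alone 12 fell and 1 rose (adjusted p = 2.91e-04; adjusted p = 0.0597 with an estimated correlation). Summed, the list was 22450 to 37850 CPM in control males 10 and 11 and control females 14, 19, 23 and 24, 12430 to 16830 in the other 6 control libraries and 13820 to 24670 in the exposed libraries. Its sum averaged 24440 ± 8916 in control and 19200 ± 2794 in exposed females (SD, n = 6), but 16960 ± 5846 in control and 18100 ± 3675 in exposed males. Sult1a1, a sulfotransferase gene, changed by -0.45 ± 0.09. Of 19 bile acid genes 3 fell, with the sterol exporter genes Abcg5 at -0.97 ± 0.20 and Abcg8 lower too. Of 21 acute phase genes 2 fell, with Orm1 at -1.37 ± 0.31. Of 21 NRF2 genes 2 fell (4 adjusted over the list alone; adjusted p = 0.165 with an estimated correlation), with Gstm1 at -0.58 ± 0.09. Of 12 heat shock genes 2 rose (adjusted p = 2.7e-04; adjusted p = 0.0625 with an estimated correlation), and of 17 lipid droplet genes 2 rose (adjusted p = 0.00282; adjusted p = 0.216 with an estimated correlation), with Fabp4 at 1.22 ± 0.18. Control males 10 and 11, control females 14 and 19 and exposed male 8 had lipid droplet sums of 748 to 955 CPM and heat shock sums of 1539 to 1800 CPM, against 1245 to 1918 and 1712 to 2363 in the other 19 PND0 libraries. Without these 5 libraries, also those with the lowest fatty acid oxidation sums, 1 heat shock gene (adjusted p = 0.00784; adjusted p = 0.289 with an estimated correlation) and 1 lipid droplet gene, Fabp4 (adjusted p = 0.0298 for the list; adjusted p = 0.312 with an estimated correlation), rose. Then 12 hypoxia and 4 respiratory chain genes rose, and 6 mature hepatocyte and 5 NRF2 genes fell. Of 31 erythroid genes 1 rose, the embryonic globin gene Hbb-y at 2.63 ± 0.44. In 23 of 43 lists no member passed over all genes tested, and camera called 15 lists, or 2 with an estimated correlation. Of those 23, 2 are the stellate (adjusted p = 0.00502; adjusted p = 0.337 with an estimated correlation) and ribosomal protein lists (adjusted p = 0.00463; adjusted p = 0.756 with an estimated correlation), which pointed up. Muscle markers, of which 0 of 10 passed, had a median of -1.80, and pancreas markers, 0 of 6, were summed highest in a control library. Muscle markers summed to 1748 CPM in control male replicate 2, 540 in exposed female replicate 13 and 188 in control female replicate 21, and pancreas markers to 438 in control female replicate 23 and 175 in exposed female replicate 18. Without the 5 libraries with muscle or pancreas markers 10 hypoxia, 1 iron and 22 respiratory chain genes rose, and 1, 3 and 0 fell, 5 Kupffer genes and 6 mature hepatocyte genes fell, and the iron list was no longer past the threshold (adjusted p = 0.103). In that setting 3 of 12 heat shock genes rose (camera adjusted p = 4.40e-06, and 0.00352 with an estimated correlation). There 6 of 19 unfolded protein genes rose (camera adjusted p = 0.0114, and 0.531 with an estimated correlation).

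**Figure D2:**
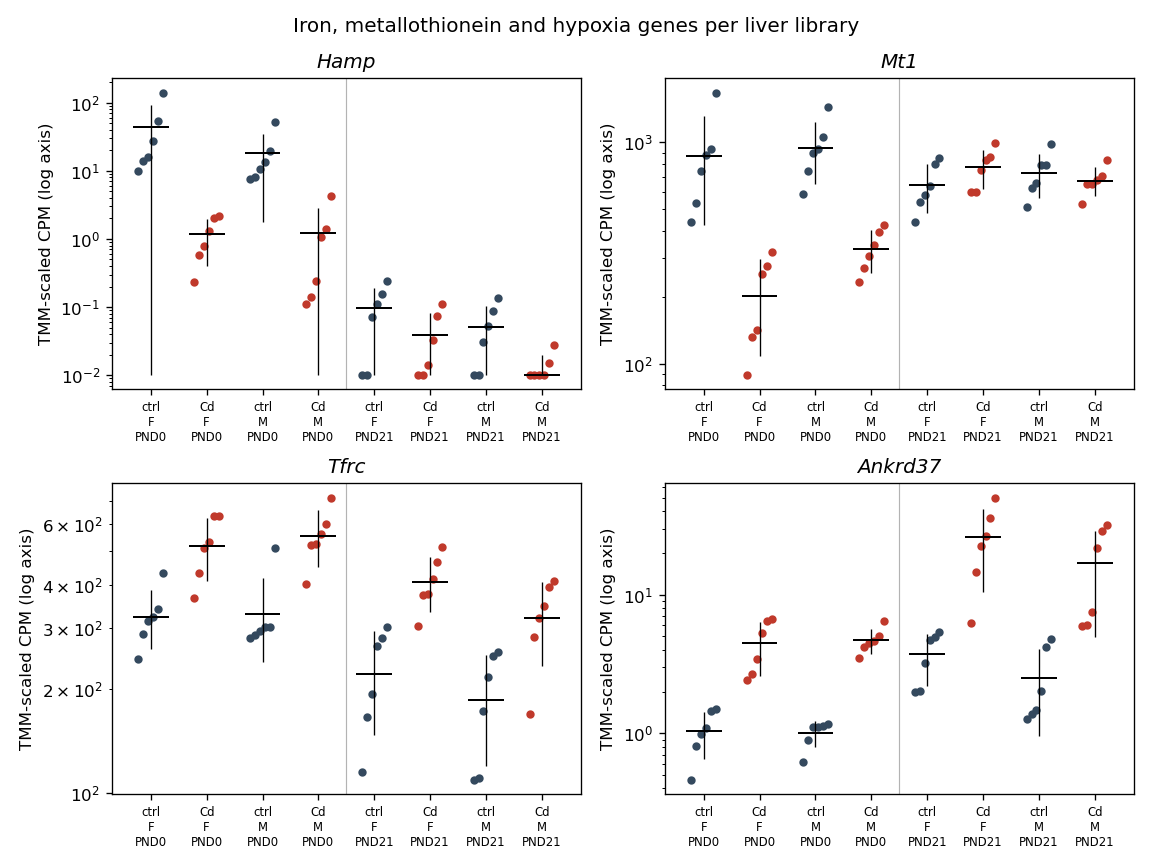
Iron, metal and hypoxia genes in CPM on a log axis, with 1 point per library by age, sex and dose (dark control, red exposed, 6 per group, placed in order of value); horizontal lines are means and vertical bars SD, with zeros and lower ends of bars drawn at 0.01 CPM. At PND0 mean Mt1 was 203 CPM in exposed and 868 in control females, while at PND21 Mt1 did not pass (log2 0.08).

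Over both sexes 364 genes rose and 216 fell at PND0 of 19084 tested, with 32 and 30 in females and 39 and 8 in males. Of these, 25 passed in both sexes, all 25 in the same direction (20 up and 5 down, against 0.0654 and 0.0126 expected for independent calls). As at PND21, calls in the sexes are not independent, because they share 1 fit and may share litters. Log2 changes correlated across genes at r = 0.247 and rho = 0.348 between the sexes; genes are not independent replicates. In females Hamp changed by -5.19 ± 0.90 (adjusted p = 0.00831), Mt1 by -2.10 ± 0.32, Mt2 by -2.06 ± 0.35 and the oestrogen receptor gene Esr1 by -1.49 ± 0.19, all lower in 6 of 6 exposed libraries. In males Mt1 changed by -1.52 ± 0.32 (adjusted p = 0.0383), Mt2 by -1.59 ± 0.34 (adjusted p = 0.0481) and the hypoxia gene Ankrd37 by 2.22 ± 0.28 (adjusted p = 3.92e-04), while Hamp (-3.95 ± 0.86, adjusted p = 0.0539) and Tfrc (0.75 ± 0.17, adjusted p = 0.0539) did not pass. Hypoxia genes rose in 5 of 20 cases in females (8 adjusted over the list alone) and 6 of 20 in males (14 adjusted over the list alone), and Mt1 fell in both. The female count of 5 became 2 without control 14, 19 or 24 or exposed 16 or 22, 3 without control 23, exposed 20 or the filter, and 1 with the 12 female libraries fitted alone. The male count of 6 became 3 without control 7 or 11, 11 with the covariate and 14 with limma-voom. Over both sexes 8 to 11 rose in the leave-outs, and 15 with the covariate or limma-voom. The male calls ended without a filter (adjusted p = 0.0975 for Mt1 and 0.116 for Mt2), for Mt1 without exposed male replicate 12 (0.117, lowest 2.72e-04 over the settings) and for Mt2 without exposed male replicate 6 (0.134, lowest 3.63e-04) and with RLE scaling (0.0508), and for both without the libraries with low fatty acid oxidation sums (0.113 and 0.104). The female Mt1 and Mt2 calls ended when only their 12 libraries were fitted (adjusted p = 0.0624 for both, lowest 1.32e-08 and 2.72e-07). For Hamp in males the settings gave adjusted p from 3.63e-04 to 0.158, and for Tfrc from 1.2e-04 to 0.165. In females Tfrc did not pass (0.68, adjusted p = 0.0973, from 0.00996 without the libraries with low fatty acid oxidation sums to 0.243 over the settings).

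Counts at PND0 moved with libraries. Without the 5 libraries with low fatty acid oxidation sums 158 genes passed in females, 173 in males and 730 over both sexes, 345 of them among the 580. In females 62 genes became 40 without control replicate 14, 35 without exposed 15, 34 without exposed 16, 41 without control 19, 32 without exposed 20, 30 without exposed 22 and 35 without control 24. In males 47 became 31 without exposed 1 or control 2, 29 without exposed 6, 28 without control 7, 117 without exposed 8 and 76 without control 10. Over both sexes 580 became 373, 326 and 994 without exposed males 1, 6 and 8, 356, 374 and 306 without exposed females 16, 20 and 22, and 366 without control female 19.

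No gene differed in its cadmium effect between the sexes at PND0 by edgeR, with 599 genes at an unadjusted p under 0.05, 1 gene by DESeq2 and 0 by limma-voom. The smallest p belonged to the zinc finger gene Zfp940, with a female minus male difference of -1.37 ± 0.25 (adjusted p = 0.293). For Hamp the difference was -1.24 ± 1.12 and for Tfrc -0.08 ± 0.23, both with an adjusted p of 1.

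Cadmium effects differed between the ages for 5294 genes of 19811 tested, 3315 with a higher and 1979 with a lower log2 change at PND21. The PND21 minus PND0 difference was 4.49 ± 0.41 for H19, 3.77 ± 0.50 for Igf2, 3.79 ± 0.42 for Dlk1 and 0.55 ± 0.16 for Plagl1 (adjusted p = 0.00721). It was 2.10 ± 0.33 for Mt2 and -0.48 ± 0.09 for Slc39a8, and did not pass for Tfrc (0.12 ± 0.22, adjusted p = 0.752). For Hamp the fit gave 2.68 ± 2.01 (adjusted p = 0.353, from 0.0285 with DESeq2 to 0.581 over the settings). Hamp was too low to test at PND21, so this value cannot decide whether its effect differed between the ages. The eosinophil gene Prg2 had 5.79 and Sult3a1 -6.12 ± 1.06. The effect was higher at PND21 for 17 of 19 fetal hepatocyte genes (adjusted p = 0.00178 with an estimated correlation), 18 of 19 Kupffer genes (adjusted p = 0.00635 with an estimated correlation) and all 15 megakaryocyte and 19 neutrophil genes, and lower for 23 of 28 respiratory chain genes (24 adjusted over the list alone; adjusted p = 0.233 with an estimated correlation). The Cdkn1c difference, 1.15 ± 0.41 (adjusted p = 0.0321), had an adjusted p of 0.0893 without PND0 control male replicate 11, 0.062 without a filter, 0.107 with limma-voom and 0.65 (0.19) without the libraries with low fatty acid oxidation sums, and 0.0193 at the lowest. Of 17011 genes tested at both ages, 352 passed at both, 232 in the same direction (162 up and 70 down, against 83.3 and 38 expected for independent calls) and 120 in opposite directions (114 expected).

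**Figure D3:**
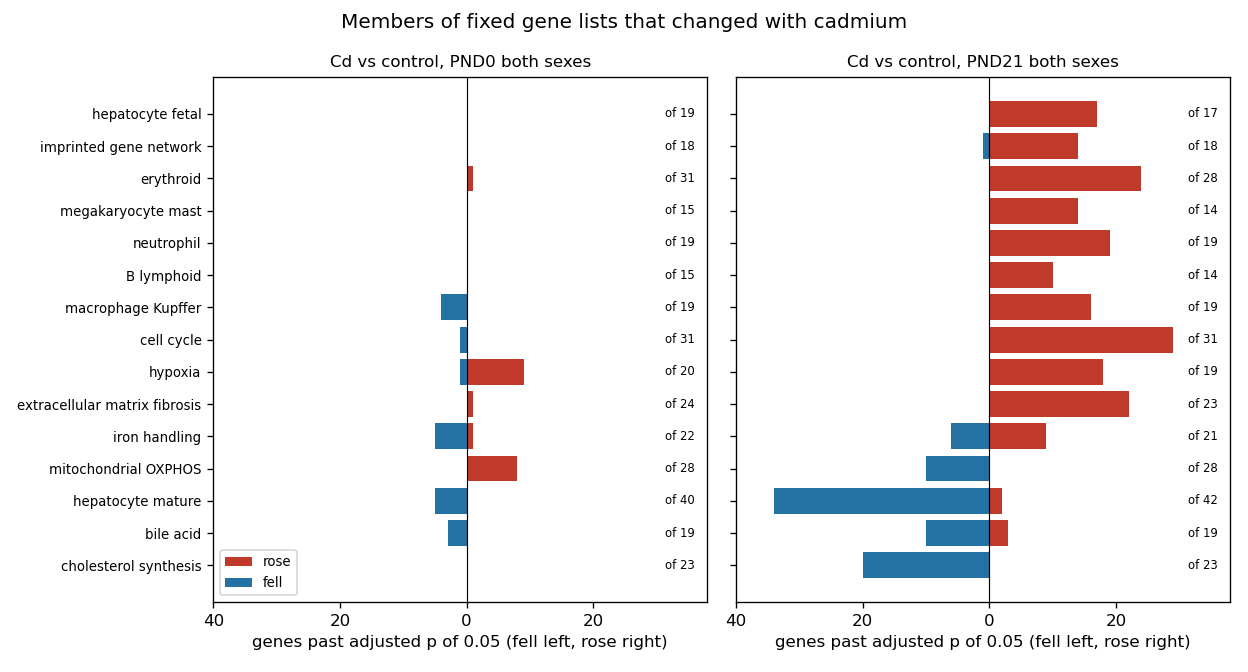
Number of members past an adjusted p of 0.05 for the cadmium effect over both sexes, for a selection of the 43 gene lists. Falls are drawn to the left and rises to the right of 0, with the number tested beside each bar, for 12 exposed and 12 control libraries at each age. The lipogenesis, NRF2, drug metabolism and heat shock lists, among others, are not drawn. At PND21 all 17 fetal hepatocyte, 14 megakaryocyte and 19 neutrophil genes rose, and 34 of 42 mature hepatocyte genes fell.

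Among controls, livers changed widely from PND0 to PND21, with 7435 genes higher and 7997 lower at PND21. Of 42 mature hepatocyte genes 41 rose and 1 fell, with the cytochrome P450 gene Cyp2c29 at 11.23 ± 0.25 and the urinary protein gene Mup3 at 12.75 ± 0.44. Of 19 fetal hepatocyte genes 18 fell and 0 rose (adjusted p = 0.00756 with an estimated correlation), and all 31 cell cycle and 15 megakaryocyte genes fell, as did 30 of 31 erythroid genes (adjusted p = 0.112 with an estimated correlation). Igf2 changed by -10.11, Dlk1 by -10.06 and Plagl1 by -3.94, and the neutrophil-lineage gene Stfa2 by -11.45 ± 0.26. These counts were equal when adjusted over the list alone.

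Between control females and males, 29 genes were higher and 21 lower in females at PND0, and 35 higher and 52 lower at PND21. Apart from Xist (11.93 ± 0.23 at PND0) and the Y-linked genes (Ddx3y -13.23), the PND0 calls included the X-linked gene Kdm6a at 0.76. At PND21 the male-biased urinary protein genes Mup20 (-2.28 ± 0.36, adjusted p = 0.0011) and Mup17 (-4.82 ± 0.81) were lower in females. Of 28 genes with adult sex bias 1 was higher and 2 were lower in females (4 and 9 adjusted over the list alone), and of 42 mature hepatocyte genes 6 were lower (10 lower and 1 higher adjusted over the list alone; adjusted p = 0.0108; adjusted p = 0.942 with an estimated correlation). Without control male replicate 32 the PND21 count fell from 87 to 53, and the calls for Sult3a1 (-2.77 ± 0.55, adjusted p = 0.0154) and Mup3 (-2.32, adjusted p = 0.0143) ended (adjusted p = 0.062 and 0.0527). Fitted on their 12 libraries alone, Sult3a1, Mup3 and Mup17 did not pass (adjusted p = 0.141, 0.128 and 0.0623; lowest over the settings 0.00495, 4.25e-06 and 2.4e-04).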

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

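The residue, dilution and maturation tests, the covariate for variation within groups and the leaving out of libraries with muscle or pancreas markers or low fatty acid oxidation sums were chosen after the result was seen.

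At PND21, fetal and blood lineage genes were higher and mature hepatocyte genes lower in exposed livers. A uniform residue of tissue like that of PND0 predicts 1 share of the PND0 level for every lineage. The median share was 11.8% (quartiles 8.90 to 19.8) for megakaryocyte genes and 3.5% (1.65 to 4.79) for B lineage genes. Erythroid (4.78%), neutrophil (6.28%) and fetal hepatocyte genes (7.5%, 1.30 to 14.4) lay between. The ratio of 3.37 lies only narrowly above the bound of 3 set after the result was seen, which argues against a uniform residue weakly. Single genes spread wider, at 15.5% for H19, 6.10% for Cdkn1c, 4.43% for Plagl1, 1.3% for Igf2, 1.27% for Dlk1 and 1.04% for Afp. For these genes the values argue against 1 uniform share. Dilution of hepatocyte RNA predicts that abundant genes fall like the mature list (median -0.61 on library totals), yet the 50 most abundant nuclear genes, with 36% of counts, had a median of -0.13 ± 0.07 (SE), which argues against dilution as the whole cause. Delayed maturation may account for part of the change. With separate control libraries for the 2 contrasts, 89.42% and 88.96% of genes called in both moved in the direction of the PND0 level (50.7% and 50.8% expected). Another 482 and 487 moved away, and the bounds set for this test, 80% and 90%, leave open whether delay is the whole change. Direction was counted by sign alone, so genes that moved past the PND0 level are included. Summed hypoxia genes moved past it, to 4333 CPM on library totals in exposed PND21 females and 3885 in males. Controls had 2547 and 2527 at PND21 and 2948 and 3060 at PND0. That argues against delay as the whole change for these genes. Across genes, which are not independent replicates, the age and cadmium changes correlated at -0.595 with shared controls and at about -0.565 and -0.569 with separate ones (covariance -0.607, -0.591 and -0.592), against -0.0732 (covariance -0.0195) simulated for shared controls without an effect; litter and a change in individual cell types stay open.

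At PND0, hypoxia genes were higher and hepcidin lower in exposed livers. Differences between pups in the main variation within groups, such as hours since birth, were tested with that component as a covariate: the median of the hypoxia list was 0.54 against 0.48 and 15 members rose against 9, which argues against them as the whole cause. RNA of muscle or pancreas was tested by leaving out the 5 libraries with their markers, where the median was 0.51 and 10 members rose. That argues against RNA of these tissues. RNA of fat, gut, kidney or adrenal was not tested in this way. Without the 5 libraries with low fatty acid oxidation sums the median was 0.62 and 12 members rose. Litter, time from birth to collection along other components, and exposure itself stay open and may contribute.

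At PND0, metallothionein genes were lower in exposed livers although cadmium is known to induce them. A lower glucocorticoid signal, which also drives these genes, is a candidate explanation: the 8 targets chosen for it had a median of -0.61, from -1.57 for Tat to -0.11 for Dusp1. Of the 8, 1 passed the threshold, Fkbp5 (-0.50 ± 0.11, adjusted p = 0.016), so this stays a hypothesis. Of the technical explanations, the component within groups and RNA of muscle or pancreas are argued against by Mt1, which stayed past the threshold over both sexes in every setting run (adjusted p at most 0.00141). Litter and metal content are not given in the sources used here and stay open.

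Other splits of the same libraries, 100 per comparison with the real 1 included, were counted. Pups and not litters were exchanged, so the splits cannot test a chance difference between litters. For 62 genes in females at PND0, 1 split called as many and the highest other called 1, and for 580 over both sexes 1 and 11. That argues against a chance assignment of pups. For 47 genes in PND0 males 2 splits called as many and the highest other called 64, more than the real count. That share is under 0.05, but the count itself fell to 28 without control male 7, so the evidence against chance is weaker there. At PND21 1 split called as many for 4764 genes in females (highest other 3710), 4937 in males (2842) and 7427 over both sexes (2), and 1 for 5294 genes differing between ages (35). Each of these argues against a chance assignment of pups, with litters left open. For the sex difference in the effect 0 genes were called, so all 100 splits at either age match that count by construction (highest other 5 at PND0 and 20 at PND21), and the splits say nothing on it. Among controls 1 split called as many for 15432 genes by age (12524) and for 87 genes by sex at PND21 (2). For 50 genes by sex at PND0 2 splits called as many; the highest called 3184, many times the real count, and points to a structure of those libraries other than sex.

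A library far from the other 5 of its group was found in 18 of 190 groups of values tested, where chance gives 9.5. Values are CPM on library totals. Plagl1 was 80.44 in PND0 control female replicate 21 (others 47.7 to 54.0) and 2.198 in PND21 control female 45 (2.94 to 3.43). Tfrc was 504.9 in PND0 control male 11 (277 to 308). H19 was 483.5 in PND21 exposed female 41 (1856 to 3729), which also had 110.8 for neutrophil genes (216 to 310). Among summed markers, muscle gave 187.5 in PND0 control female 21, 1748 in control male 2 and 540.1 in exposed female 13. Pancreas gave 438.1 in PND0 control female 23, 175.1 in exposed female 18 and 7.314 in PND21 control female 44. Gut gave 33.08 in PND0 exposed male 8 (363 to 569) and 917.3 in PND21 control male 25 (473 to 550). Low gut sums were also found in 4 of the 12 PND0 controls, males 10 and 11 (34.1 and 45.3) and females 14 and 19 (48.3 and 67.1). These 5 libraries had fatty acid oxidation sums of 7569 to 9862, against 10530 to 21790 in the other 19 PND0 libraries. Endothelial genes gave 823.3 in PND21 control female 37 (942 to 991), megakaryocyte genes 125.3 in control female 40 (67.9 to 72.5), stellate genes 805.6 in control female 45 (1012 to 1073) and T and NK genes 7.449 in exposed female 47 (5.18 to 5.90). The library total was 79.7 M counts in PND0 control male 4 (58.7 to 64.6).

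The cadmium effect differed between ages, tested as an interaction, for 5294 genes, with PND21 minus PND0 differences of 0.5455 for Plagl1, 1.885 for Mt1, 2.097 for Mt2, -0.484 for Slc39a8, 3.771 for Igf2, 4.494 for H19, 1.154 for Cdkn1c and 3.793 for Dlk1.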

How the results depend on the processing

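The covariate for variation within groups and the leaving out of libraries with muscle or pancreas markers or low fatty acid oxidation sums were chosen after the result was seen. Counts stayed within 1.5 times under every setting run for cadmium at PND21 in females (3735 to 5843), males (3581 to 5518) and both sexes (5403 to 8219), for the age difference in the effect (4547 to 6357) and for age among controls (11609 to 18133). Leaving out 1 library at a time gave 3902 to 5240, 4129 to 5421, 7018 to 7832, 4940 to 5690 and 15391 to 15545 in the same order. At PND0 counts moved. For females (62) DESeq2 gave 218, no filter 35, limma-voom 142, 12 libraries 32, the covariate 190 libraries with other tissue left out 118 and those with low oxidation sums left out 158; leave-outs gave 30 to 74. For males (47) DESeq2 gave 180, limma-voom 708, the covariate 237 and libraries with low oxidation sums left out 173; leave-outs gave 28 to 117. For both sexes (580) DESeq2 gave 1129, limma-voom 1664, the covariate 1365, no filter 327, the 48-library fit 1099 and libraries with other tissue left out 1092; leave-outs gave 306 to 994. Of the 580 genes, DESeq2 kept 572, the covariate 578, the 48-library fit 491 and no filter 318. The sex difference in the effect gave 1 gene with DESeq2 at either age. Female against male controls gave 78 with DESeq2, 166 with limma-voom, 31 with 12 libraries and 26 with libraries with other tissue left out at PND0 (leave-outs 41 to 55), and 207 and 202 with DESeq2 and limma-voom at PND21 (leave-outs 53 to 126). Bag3 (0.00499) and Dnaja1 (0.0167), both falls at PND21, changed sign with the covariate. Leaving out PND0 control male replicate 3 gave 34 genes in males and 425 over both sexes. Without a filter the median of all genes by age among controls shifted by -0.194. That median covers 36528 genes, against 19811 with the filter, so it does not show a shift of the same genes. Whether scaling also played a part was not tested. Of 43 lists, the estimated correlation left 5 of 19 camera calls at PND21 and 2 of 15 at PND0 over both sexes. Of 164 named genes past the threshold at PND21 over both sexes 144 stayed past it in every setting and leave-out in which they were tested, and 34 of 49 at PND0. A gene that a setting filtered out was not counted as lost there. Low counts limit the estimates for genes near 0 in 1 group.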

Other observations

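The values in this part were picked out after the result was seen. Adrenomedullin 2 (Adm2, ENSMUSG00000054136), a vasodilator peptide gene, had 0 counts in all 12 PND21 control libraries and 2106 in the 12 exposed, at least 672-fold higher against a floor of 3 counts over the control group. At PND0 it had 406 and 501 counts over control females and males and 941 and 1010 over the exposed groups. Mup10 (ENSMUSG00000078680), a urinary protein gene, had 0 counts in the 12 exposed and 1490 in the 12 control libraries at PND21, 1397 of them in males, at least 519-fold lower against the same floor. Reads of Mup genes are hard to assign to 1 member.

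At PND0 over both sexes, Esr1 changed by -1.12 ± 0.13 (SE, adjusted p = 1.7e-05, 12 exposed and 12 control libraries), the lactate exporter gene Slc16a3 by 1.02 ± 0.14 and the oxygen sensor gene Egln3 by 1.44 ± 0.20. These genes were not followed through the other settings in this comparison.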
